A study of Homo sapiens with 4 samples.

How the data were processed

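Total RNA of 2 human prostate cancer cell lines was measured on 4 single-colour (Cy3) Agilent whole-genome arrays, with 1 array per group and no replicate. PC3 is an androgen-independent line from a bone metastasis. C4-2B is a metastatic subline of LNCaP, a line that responds to androgen. Each line carried a lentivirus with either GFP alone or GFP and the full-length HIC1 coding sequence under the SFFV promoter, and strongly GFP-positive cells had been sorted, per the labels' protocols. The labels give LNCaP as the cell line of all 4 samples and name PC3 or C4-2B as the subline. The groups were PC3-GFP, PC3-HIC1, C4-2B-GFP and C4-2B-HIC1, and these names stand throughout for what the labels say of an array. All 4 arrays lay on 1 slide and were read in 1 scan, per the file headers, so no batch could be told from the design.

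Spot values were fluorescence intensities on a linear scale made with Agilent Feature Extraction 10.7.3.1, which subtracted background and corrected spatial trends within each array, per the file headers. The authors deposited a second table of log2 values for the same arrays. Its columns shared a median of 7.21 and a 75th percentile of 10.1, and their Spearman correlation with the scanner values of the same array was 1.00 to 3 digits. These equal quantiles are those of quantile-normalised values, but the step is not given in the sources used here. That table served as an alternative, and the scanner values as the main source.

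Of 45015 spots per array, 43376 were not controls, and these held 41000 distinct probes. Spots marked by the software as non-uniform or as population outliers were left out, between 80 and 140 non-control spots per array, and 81 probes carried such a mark on some array. No spot was saturated. Values were log2 of the background-subtracted intensity, averaged over repeated spots, minus the array's 75th percentile over all non-control probes. Probes were named through their transcript accession in the RefSeq gene table supplied for names, which gave a symbol to 27210 probes (66.4%) and left 13790 without one. The array design uses build hg19 and the name table a later assembly, so no coordinates are given. A gene took the value of its probe with the highest mean signal over the 4 arrays, which gave 18174 genes, 6738 of them on more than 1 probe. XIST and genes of the Y chromosome were not examined by name.

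The depth of an array is its signal over background. Median raw signals were 165, 180, 144 and 177 units on the PC3-GFP, PC3-HIC1, C4-2B-GFP and C4-2B-HIC1 arrays, against median backgrounds of 43, 45, 44.5 and 40 units. The software called 73.8%, 74.7%, 69.5% and 72.7% of probes well above background. Probes printed 10 times within an array had a median SD between spots of 0.03 to 0.05 log2, which covers spotting and scanning only. The number of arrays, not this spread, limits the precision.

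With 1 array per group no replicate test exists within a line. Genes in a line were therefore called higher or lower by size alone, at 2-fold or more with both arrays well above background, with no p-value. A gene well above background on only 1 of the arrays got a lower bound on its fold, against the faintest signal called well above background on the other array. Overlap between the lines was counted over genes well above background on all 4 arrays and set beside the product of the shares of the lines. Over both lines, an additive model (cell line plus HIC1, with the cell line as block, since each GFP array is the control of its own line) was fitted with limma 3.58.1 in R 4.3.3 to 14752 genes well above background on at least 2 arrays. It leaves 1 residual degree of freedom per gene, the difference between the effects in the lines. Calls needed a Benjamini-Hochberg adjusted p under 0.05. The same fit gave PC3 against C4-2B.

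A set of 30 gene lists was fixed before the data were examined, as were the groups, the tests of the comparisons and the rule for naming genes. The tests that weigh explanations were chosen later. In each line the median log2 ratio of a list was placed among 10000 random lists of the same size, matched in 20 bins of mean expression, and called above or below when outside their central 95%. Lists with fewer than 5 measured genes were left out of this. Over both lines the lists were tested with camera from limma, with a preset correlation of 0.01 and with an estimated correlation. The rule for named genes took HIC1, the 10 highest and 10 lowest ratios in each line, the 5 largest bounds per direction and line, the 10 largest shared changes per direction, up to 4 members of each list, the 10 largest differences between the lines each way, and up to 5 genes per opposed direction. Results of some genes under this rule are not reported here.

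The fit was tested on simulated data for the 14752 genes, with 50 genes changed at each of 2-, 4-, 8- and 16-fold. With a noise SD of 0.05 log2 it recovered 100% at each size, and with 0.2 log2 it recovered 96.0% at 2-fold and 100% at the larger sizes, with 8 false calls in each case. With the residual SDs of the real arrays it recovered 0 of 50 at every size. The alternatives were a normexp background correction (offset 50), quantile normalisation, centring on the median, the authors' table, a looser background filter, the mean over probes, 3-fold and 1.5-fold thresholds, an intensity trend in the prior variance, genes well above background on all 4 arrays only, a fit with no cell line term, and the mean of a list in place of its median. The files hold median and not mean spot signals, so normexp was run on median signals. A normexp fit without spots of high background, the genes brighter than the median, and a crossed pairing of the arrays were added after seeing the data. Tables were handled with the data.table package (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.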

Results

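Cultured prostate cancer cells of 4 groups were profiled, with 1 array for each of PC3-GFP, PC3-HIC1, C4-2B-GFP and C4-2B-HIC1. The question given by the study's title is which genes HIC1, a zinc-finger transcriptional repressor whose promoter is methylated in many cancers, regulates in these cells. Between 69.5% and 74.7% of the 41000 probes lay well above background on an array. Levels are log2 values relative to the array's 75th percentile, and ratios are the HIC1 array over the GFP array of the same line. No value has a replicate, so no error between cultures can be given. Within an array, spotting and scanning gave a ratio an SD of 0.07 log2 in PC3 and 0.05 log2 in C4-2B.

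HIC1 transcript was higher on both HIC1 arrays than on the GFP array of the same line. Its brightest probe read -3.23 on PC3-GFP and -1.95 on PC3-HIC1, a ratio of 1.28 log2 or 2.42-fold. In C4-2B it read -1.99 on the GFP array and -0.21 on the HIC1 array, a ratio of 1.79 log2 or 3.45-fold. A second, dimmer HIC1 probe was 1.68-fold higher in PC3 and at least 2.07-fold higher in C4-2B. By size, HIC1 ranked 431 from the top of 14421 measured genes in PC3 and 625 from the top of 13474 in C4-2B. The files do not say whether these probes lie within the introduced coding sequence, so the size of the difference does not measure the transgene.

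Markers of the lines went against the labels of the C4-2B arrays. KLK3, the gene of prostate-specific antigen and abundant in LNCaP cells, was not well above background on any array, with a highest level of -7.98 on C4-2B-HIC1. CAV1, a caveolar gene typical of PC3, read 2.59, 1.42, 3.56 and 0.69 on PC3-GFP, PC3-HIC1, C4-2B-GFP and C4-2B-HIC1. GSTP1, which is silenced in LNCaP cells, was among the brightest genes on all 4 arrays, between 6.73 and 6.86. Every direction given here therefore compares arrays by their labels, and the identity of the cells behind the C4-2B labels is not borne out by these genes.

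**Figure D1:**
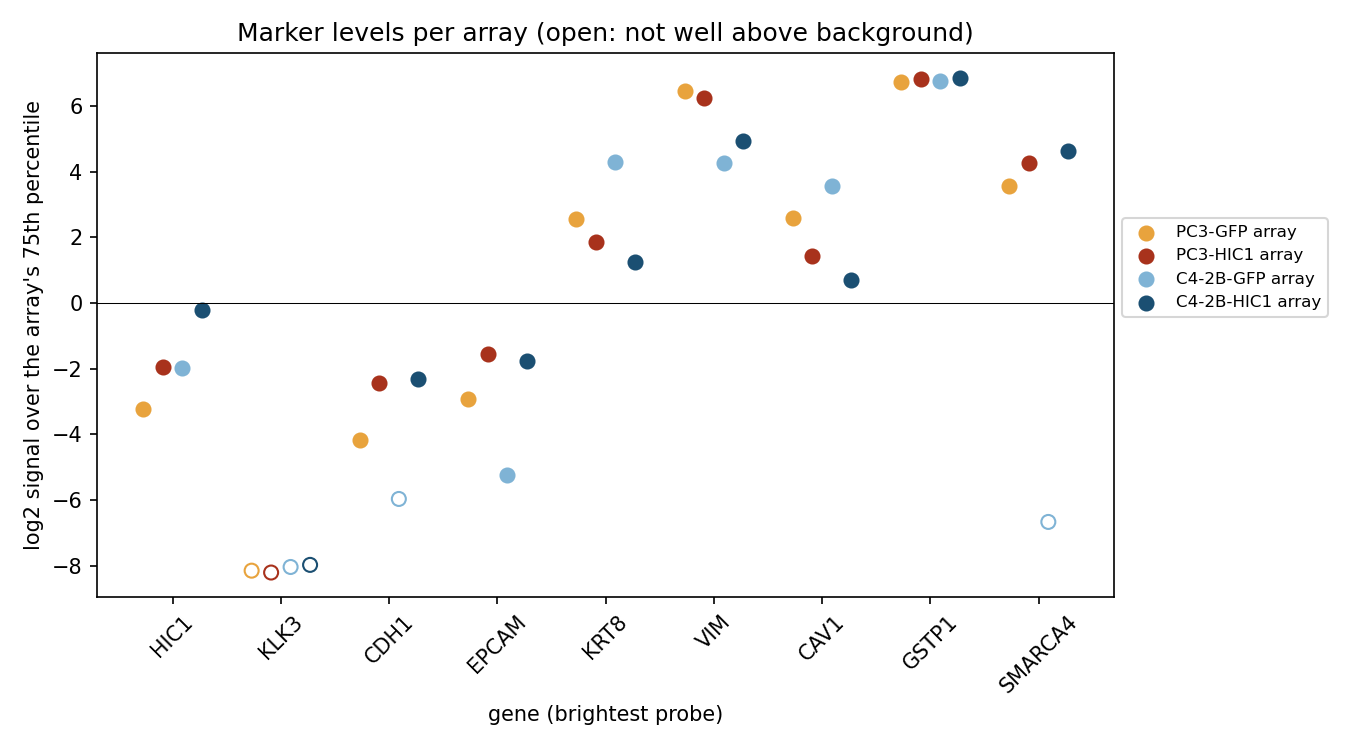
Log2 level of 9 genes relative to each array's 75th percentile (vertical axis), 1 point per array and gene at its brightest probe; open points were not well above background. HIC1 is higher on each HIC1 array than on its GFP array, KLK3 is open on all 4 arrays with a highest level of -7.98, and SMARCA4 is open on C4-2B-GFP only.

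In PC3, the HIC1 array showed higher levels of the growth-arrest gene CDKN1C, the AP-1 subunit gene FOS and the transcription factor gene GATA5. It showed lower levels of S100A2, TGFBI and ID1. Among genes well above background on both PC3 arrays, FOS had the highest log2 ratio, 3.38, followed by STON1 at 3.18. CDKN1C, which encodes the cyclin-dependent kinase inhibitor p57, stood at 2.69, the integrin gene ITGA8 at 2.58 and the transcription factor gene GATA5 at 2.54. ARAP3 (2.50), SYT6 (2.47), BNC2 (2.45), FMN2 (2.42) and TMEM255A (2.35) completed the 10 highest. The lowest ratio among the same genes, -4.12, belonged to the zinc-finger gene ZNF224. Its level was 1.55 on PC3-GFP and between -2.87 and -2.54 on the other arrays. KRTAP2-3 followed at -3.59, the calcium-binding protein gene S100A2 at -3.33, the matrix protein gene TGFBI at -2.54, the linker histone gene H1-5 at -2.30, the transcription factor gene ETS1 at -2.23, NAV3 at -2.07 and ID1, an inhibitor of basic helix-loop-helix factors, at -2.02. ACTG2 (-2.73) and S100A3 (-2.46) were also among the lowest, but with the normexp background correction as planned their ratios turned to 0.38 and 0.31. A few spots distorted that fit. For named genes at least 2-fold apart and lists outside their range, no direction turned when normexp was fitted without spots of high background.

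By size, 874 of 14421 measured genes were at least 2-fold higher in PC3 with HIC1 and 189 were at least 2-fold lower, 7.37% of the genes in all. A further 129 genes were higher and 66 lower by at least 2-fold as bounds, because only 1 array lay well above background. The interferon-induced GTPase gene GBP2 was at least 10.9-fold higher, SMTNL2 at least 7.78-fold, SPTBN5 7.51-fold and SIGLEC7 7.38-fold. In C4-2B, GBP2 went the other way, at least 7.59-fold lower as a bound. In PC3, PLA2R1 was at least 6.34-fold lower, MYH6 6.21-fold, CTRB1 5.63-fold, GTSF1 5.55-fold and OR2T8 5.54-fold. Several of these bounds rest on the signal of a single array. MYH6, CTRB1 and OR2T8 were well above background on PC3-GFP only, and SPTBN5 and SIGLEC7 on PC3-HIC1 only. The other probes of MYH6, PLA2R1 and SIGLEC7 were not well above background on any array. Of 327 other measured probes for the genes that passed the size threshold, 303 (92.7%) had the same direction, 164 of them by at least 2-fold. Another probe well above background on both PC3 arrays stood at 0.38 for FMN2 and 0.26 for SYT6, against 2.42 and 2.47. Higher genes made up 82.2% of calls, against 75 higher and 73 lower among genes brighter than the median. The counts were 339 higher and 109 lower with normexp fitted without spots of high background, and 81 and 111 with normexp as planned, a fit that a few spots distorted.

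Among the gene lists in PC3, the unfolded protein and amino acid stress response was higher in 18 of 19 measured members, with a median of 0.64 log2, above the central 95% of random lists (-0.20 to 0.10). VLDLR (1.97), DDIT4 (1.66), SESN2 (1.42) and ATF3 (1.42) led it. Wnt pathway genes (median 0.64, 14 of 18 higher) and Notch pathway genes (median 0.63, 9 of 10 higher) were also above their random ranges. WNT11 stood at 2.03, but at 0.29 on its second probe. WNT3A stood at 1.996 and the Wnt inhibitor gene SFRP1 at 1.91, with DKK1, another inhibitor, at -1.71. The Notch ligand genes DLL1 and JAG2 stood at 2.04 and 1.41. The mesenchymal and invasion list was above by its median (0.53, 12 of 17 higher) and inside its range by its mean (0.30). LOX stood at 1.61, SNAI1 at 1.44 and SPARC at 1.15, although TGFBI, also a member, was among the lowest genes. As bounds, 2 further members of this list were lower and 0 higher. The prostate luminal list, led by NPY at 1.37 and HOXB13 at 1.09, was above by its median (0.59, 7 of 13 higher) and inside by its mean (0.31). The hypoxia and glycolysis list (median 0.19, 14 of 20 higher), led by CA12 at 1.95, was above as well. The heat shock and immediate early list (median 0.23, 12 of 19 higher, with FOS, EGR2 at 1.63 and EGR1 at 0.98) turned to -0.07 with normexp. The ribosomal protein list (median 0.04, 18 of 24 higher) turned to -0.29 with normexp and -0.03 with centring on the median.

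Lists below the random range in PC3 were led by the prostate basal and PC3-type list, lower in 12 of 16 members with a median of -0.83. S100A2, the laminin gene LAMB3 (-1.24), CAV1 (-1.17) and ANXA1 (-0.99) led it. Metallothioneins, which bind zinc and copper, were lower in 9 of 10 members (median -0.52, MT1M -1.49, MT1E -1.05). Mitosis genes were lower in 19 of 21 members by small amounts (median -0.26), with CDC20 at -0.75 and MKI67 at -0.70 and 0 members 2-fold lower. TGF-beta response genes had a median of -0.34 (13 of 19 lower, with ID1 and INHBA at -2.02 and -1.93 but BMP4 at 1.45), which turned to 0.01 with normexp. Cancer-testis antigens had a median of -0.88 (6 of 7 lower, MAGEA1 and MAGEA4 at -1.42, PRAME at 0.95), which turned to 0.42 with normexp. The list of HIC1 targets from the literature was inside its random range in PC3 (median 0.08), with CDKN1C and GEM at 2.69 and 2.19, TP53INP1 at 1.13 and SOX9 at -1.23.

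In C4-2B, the array labelled HIC1 showed far higher levels of UCHL1, GAL and HEY1 and lower levels of chemokine, protease and basal-type genes than the array labelled GFP. Among genes well above background on both C4-2B arrays, UCHL1, a ubiquitin hydrolase of neurons, had the highest log2 ratio, 10.54. The neuropeptide gene GAL followed at 9.12 and the Notch target HEY1 at 8.42. RAMP1 (7.50), MGST2 (7.39), ARHGAP22 (7.23), the carbonic anhydrase gene CA2 (7.13), SERPINF1 (7.02), PLAGL1 (6.96) and TBX1 (6.89) came next. Among the same genes, the chemokine gene CCL2 had the lowest ratio, -6.66, with levels of 5.73 on C4-2B-GFP and -0.93 on C4-2B-HIC1. Below it stood NNMT (-6.19), the basal keratin gene KRT17 (-5.92), MARCHF4 (-5.17), ANXA3 (-5.001), NPTX1 (-4.99), the cytokine gene IL11 (-4.90), FILIP1 (-4.85), ACTG2 (-4.85) and the protease inhibitor gene SERPINB2 (-4.81). As bounds, the neurofilament gene NEFM was at least 805-fold higher, CKMT1A 410.4-fold, DPYSL5 340.1-fold, AUTS2 243-fold and PNMA3 226-fold. CCL7 was at least 139.99-fold lower, GBP1 41.4-fold, GTSF1 29.1-fold, KRT16P2 20.8-fold and RBM24 20.03-fold.

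By size, 1465 of 13474 measured genes were at least 2-fold higher in C4-2B and 1379 at least 2-fold lower, 21.1% of the genes in all. A further 687 were higher and 164 lower by at least 2-fold as bounds. Of 1185 other measured probes for the called genes, 1149 (97.0%) had the same direction, 808 of them by at least 2-fold. VIM, which was under 2-fold by its brightest probe and so not among these genes, stood at 0.68 there and at -1.71 on its second probe. With centring on the median the split was 1074 higher against 2148 lower, and with normexp as planned 3990 genes were higher.

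The chemokine, cytokine and receptor list was lower in 15 of 16 measured members, 13 of them by at least 2-fold, with a median of -2.09 against a random range of -0.40 to 0.38. CCL2, IL11, CCL20 (-3.56) and ICAM1 (-2.49) led it. As bounds, 2 further members were lower and 3 higher: CXCR4 by at least 41.5-fold, IL6R by 3.06-fold and CXCL12 by 2.98-fold. The prostate basal and PC3-type list was lower in 14 of 16 members (median -2.05), with TP63, the basal-cell transcription factor gene, at -3.89, S100A2 at -3.27, ANXA1 at -3.24 and LAMB3 at -2.92. Interferon-stimulated genes were lower in 12 of 14 members (median -1.77, ISG15 -2.30, IFIH1 -2.28), with 2 further members higher and 1 lower as bounds. Matrix proteases and their inhibitors were lower in 11 of 12 measured members (median -1.33), with 1 further member lower and 1, the inhibitor gene TIMP3, at least 17.5-fold higher as bounds, and with the collagenase gene MMP1 at -4.51, the stromelysin gene MMP3 at -4.54 and the urokinase receptor gene PLAUR at -2.64. Metallothioneins (median -1.48, 9 of 10 lower), TGF-beta response genes (median -1.32, 14 of 18 lower) and mitosis genes (median -0.56, 18 of 21 lower) were below the random range as in PC3, where the TGF-beta median turned to 0.01 with normexp. Within the TGF-beta list TGFB2 and INHBA stood at -4.55 and -3.30 while BMP2 stood at 3.41, and in the mitosis list MKI67 and KIF20A stood at -1.26 and -1.13. Epithelial adhesion genes had a median of -0.48 (10 of 16 lower), which turned to 0.65 with normexp, and the list was inside its range by the mean (-0.39). Its members moved apart, with KRT8 at -3.03 and CDH3 at -3.21 but ESRP2 at 3.97 and EPCAM at 3.47. As a bound, 1 further member, the cadherin gene CDH1, was at least 12.6-fold higher, and its ratio in PC3 was 1.72. Cancer-testis antigens had a median of -1.72 (4 of 7 lower), which turned to 0.40 with normexp.

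The HIC1 targets from the literature had a median of -0.93 in C4-2B (9 of 13 lower), below the random range, which turned to 0.18 with normexp, and the mean of -0.28 was inside its range. EFNA1, a known direct target encoding an ephrin ligand, stood at -1.80 and SOX9 at -1.71. SNAI2 and CDKN1C went the other way, at 3.55 and 3.33. In PC3, EFNA1 was higher, at 0.47, and SOX9 lower, at -1.23. Lists above the random range in C4-2B were mesenchymal and invasion (median 1.02, 10 of 16 higher, but inside by its mean of 0.53), the unfolded protein and amino acid stress response (0.66, 14 of 18 higher) and chromatin repressor complexes (0.38, 15 of 19 higher). The transcription factor genes SNAI2, SNAI1 (3.45) and ZEB2 (3.01) led the first, with TGFBI at -4.32 and, as bounds, 2 further members lower and 1 higher. SESN2 (2.47), ATF3 (2.10) and DDIT4 (1.75) led the stress response, and CEBPB stood at -1.38. The corepressor gene BCOR (2.28), RBBP7 (1.65) and the DNA methyltransferase gene DNMT3B (1.38) led the repressor list, whose PC3 median of 0.05 was inside its range and whose PC3 mean of 0.19 was above it. Wnt and Notch genes were inside their ranges in C4-2B (medians 0.44 and 0.24, the Notch mean of 1.47 above its range), with 4 further members of each list higher, and 1 of the Notch list lower, only as bounds.

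**Figure D2:**
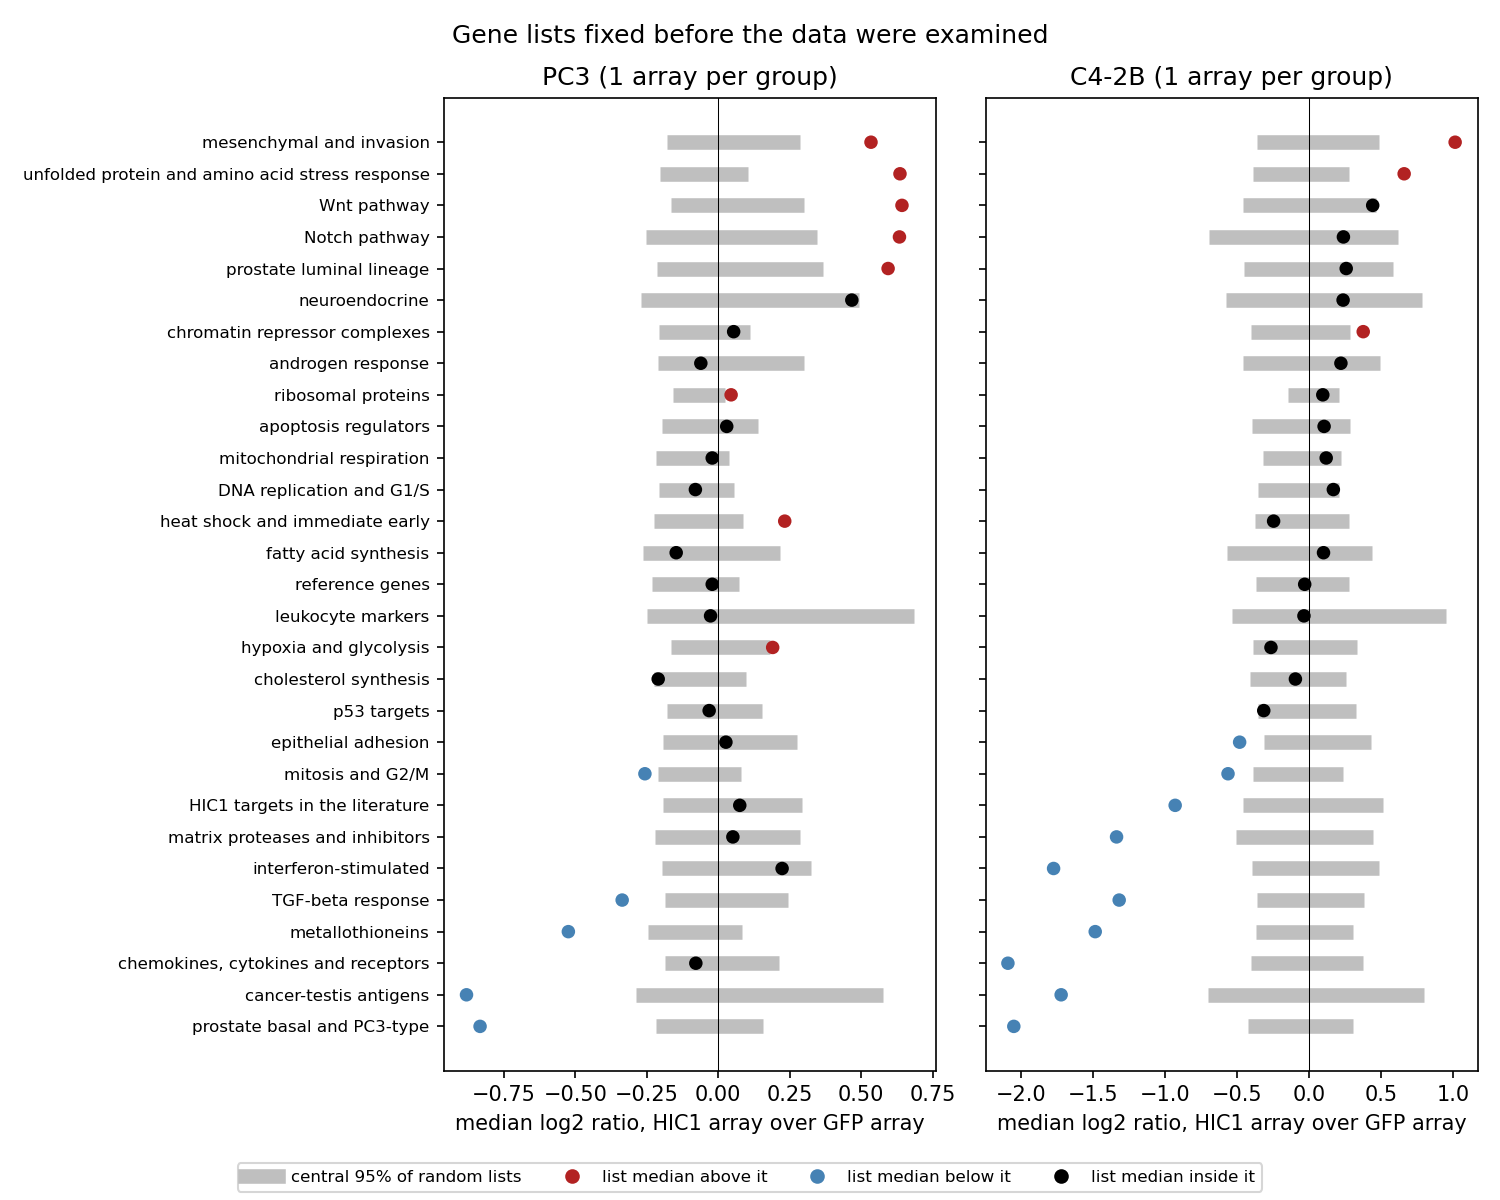
Median log2 ratio of each gene list, HIC1 array over GFP array (horizontal axis), in PC3 and C4-2B; grey bars show the central 95% of 10000 random lists matched on expression, and points are red above, blue below and black inside that range. The prostate basal and PC3-type list lies below in both lines, at -0.83 and -2.05. The unfolded protein and amino acid stress response lies above in both, at 0.64 and 0.66. With normexp as planned the PC3 medians of the TGF-beta, cancer-testis, heat shock and ribosomal lists changed sign. So did the C4-2B medians of the HIC1 target, epithelial and cancer-testis lists. None of these changed sign with normexp fitted without spots of high background.

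Lists inside the random range in both lines were DNA replication and G1/S (medians -0.08 in PC3 and 0.17 in C4-2B), p53 targets (-0.03 and -0.31), androgen response (-0.06 and 0.22), neuroendocrine (0.47 and 0.24), cholesterol synthesis (-0.21 and -0.09), fatty acid synthesis (-0.15 and 0.10), apoptosis regulators (0.03 and 0.11), mitochondrial respiration (-0.02 and 0.12), reference genes (-0.02 and -0.03) and leukocyte markers (-0.03 and -0.03). Of the lists called in C4-2B alone, chemokines (-0.08), interferon-stimulated genes (0.22), matrix proteases (0.05) and epithelial adhesion (0.03) were inside in PC3. In C4-2B the luminal (0.26), hypoxia (-0.26), heat shock (-0.24) and ribosomal (0.10) lists were inside. By the mean, the neuroendocrine list (1.25) was above and the heat shock list (-0.48) below in C4-2B. Mean and median differed in sign in PC3 for the p53, androgen, chemokine and leukocyte lists and in C4-2B for apoptosis regulators. No direction is read from a median inside its range, and several of these medians changed sign with normexp, centring or the authors' values. Whether a list differed between the lines was not tested. Fibroblast and endothelial markers had fewer than 5 measured members in each line, among them COL3A1 at 1.56 in PC3 and 0.19 in C4-2B.

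Genes that were higher with HIC1 in both lines included the cell cycle inhibitor gene CDKN1C, the Wnt ligand gene WNT11 and the Notch ligand gene DLL1, and those lower in both included S100A2, TGFBI and ETS1. CDKN1C had log2 ratios of 2.69 in PC3 and 3.33 in C4-2B, BNC2 2.45 and 2.21, the glycosyltransferase gene MGAT3 2.18 and 4.26, ABCG4 2.16 and 2.45, the kallikrein gene KLK1 2.14 and 2.94, and KCNS3 2.19 and 2.10. DLL1 stood at 2.04 and 2.86, WNT11 at 2.03 and 3.79, KLHL41 at 2.01 and 3.001, and BSPRY at 1.999 and 3.91. The second probes of WNT11 (0.29 and 0.96) and BSPRY (0.57 and 1.30) were higher by less. KRTAP2-3 stood at -3.59 and -4.47, S100A2 at -3.33 and -3.27, TGFBI at -2.54 and -4.32, H1-5 at -2.30 and -3.08, ETS1 at -2.23 and -3.11, NAV3 at -2.07 and -3.67, ID1 at -2.02 and -2.49, and MIR23AHG, the host of a microRNA cluster, at -2.004 and -2.81. ACTG2 (-2.73 and -4.85) and S100A3 (-2.46 and -3.16) belong to this group too, but with normexp ACTG2 turned to 0.38 in PC3 and S100A3 to 0.31 and 0.64.

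Of 13425 genes well above background on all 4 arrays, 349 were at least 2-fold higher in both lines, where independent changes would give 56.8, and 141 were lower in both, where they would give 17.2. Within these 13425 genes, 523 were higher and 168 lower in PC3, so the shared genes were 66.7% and 83.9% of them. In opposite directions, 26 genes were higher in PC3 and lower in C4-2B, and 1 gene, SCEL, the reverse. Across genes, which are not independent replicates, the ratios of the lines had a Pearson r of 0.61 and a Spearman rho of 0.59, and 70.0% of genes had the same sign. The ratios share no array, but the HIC1 arrays of the lines were nearly alike (r 0.990 across probes, 302 genes 2-fold apart). Such likeness can by itself give an overlap above that of independent changes. The excess therefore does not show 2 separate responses to HIC1. With normexp as planned 45 genes were higher in both, and 51 among genes brighter than the median.

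**Figure D3:**
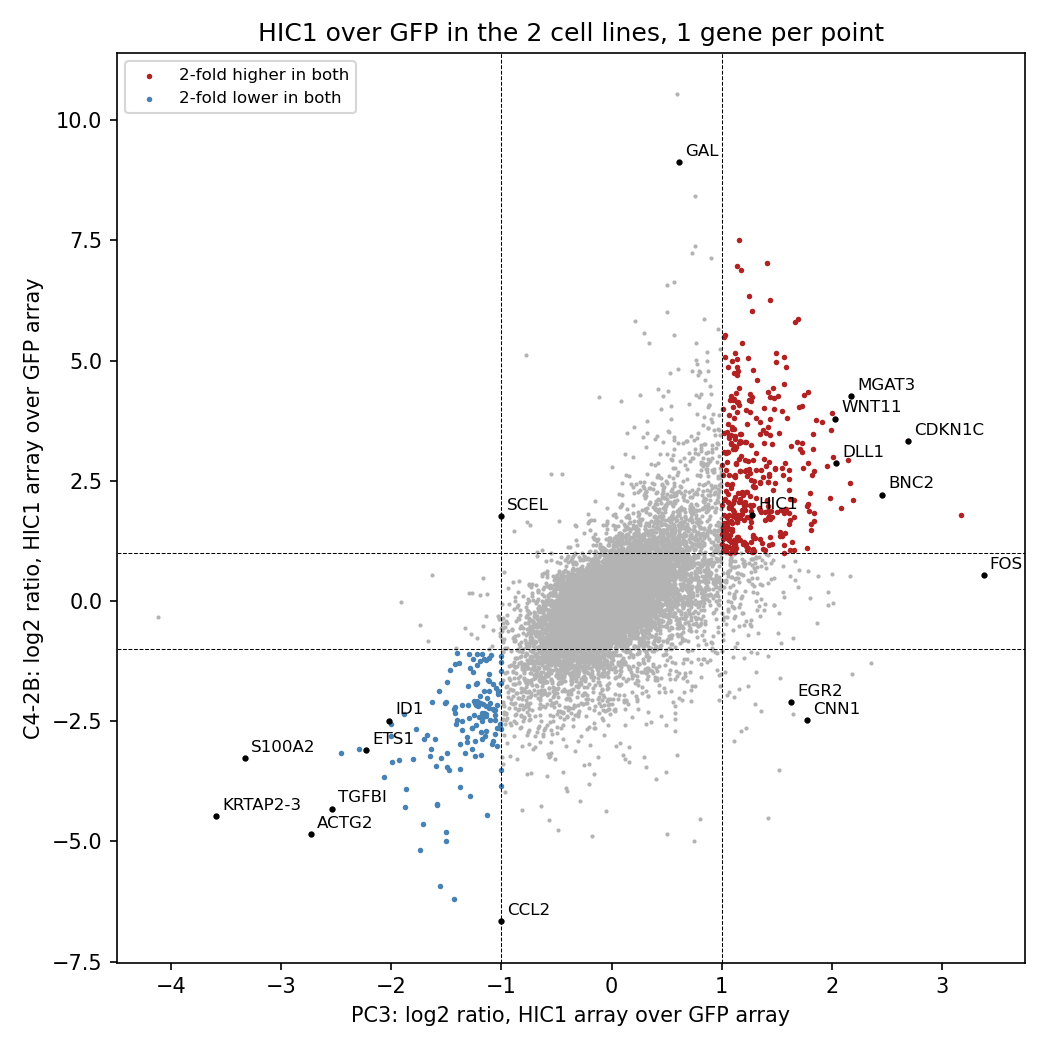
Log2 ratio of the HIC1 array over the GFP array in PC3 (horizontal axis) and C4-2B (vertical axis), 1 point per gene well above background on all 4 arrays; dashed lines mark 2-fold. The 349 genes higher in both lines are red and the 141 lower in both are blue, with CDKN1C at 2.69 and 3.33 and S100A2 at -3.33 and -3.27. With normexp as planned ACTG2 in PC3, SCEL in PC3, and CNN1 and EGR2 in C4-2B change sign. None of these does so with normexp fitted without spots of high background.

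Over both lines, no single gene passed the additive test. Stress response genes higher and basal, metallothionein and mitosis genes lower as groups passed only with a preset correlation in camera. With a correlation estimated from 1 residual degree of freedom, which cannot decide on them, camera gave an adjusted p = 0.893. S100A2 had a mean ratio of -3.30 (SE 0.21), KRTAP2-3 of -4.03 and CDKN1C of 3.01 (SE 0.28), each in the same direction in both lines. With limma, 0 of 14752 genes passed for HIC1 over GFP, 1496 had an unadjusted p under 0.05 where 737.6 would by chance, and the smallest adjusted p was 0.429. With the cell line term left out, limma also gave 0 calls, with 2489 genes at an unadjusted p under 0.05. The single residual degree of freedom is the difference between the lines, which was large, and the simulated data showed that folds up to 16 could not be called against it.

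With camera and the preset correlation, 8 of the 30 lists passed. Lower as groups were the prostate basal and PC3-type list (adjusted p = 3.07e-05, 11 of 16 members lower in both lines), metallothioneins (adjusted p = 0.000211, 9 of 10), mitosis (adjusted p = 0.00117, 18 of 21), TGF-beta response (adjusted p = 0.0118, 14 of 20), chemokines and cytokines (adjusted p = 0.0231, 10 of 21) and cancer-testis antigens (adjusted p = 0.0286, 5 of 8), whose medians turned to 0.42 in PC3 and 0.40 in C4-2B with normexp. Higher as groups were the unfolded protein and amino acid stress response (adjusted p = 0.000361, 14 of 19 members higher in both lines) and the Wnt pathway (adjusted p = 0.0187, 14 of 18). With an estimated correlation every one of these calls was lost, at adjusted p = 0.893. That correlation was estimated from the single residual degree of freedom. It came out at 1 for metallothioneins and at -0.0526 for the stress response, which lost its call even so. The loss therefore does not show that correlation among genes made the calls, and it does not decide between the settings. The other 22 lists did not pass with the preset correlation, the nearest being matrix proteases (adjusted p = 0.0746), Notch (0.116), fibroblast and endothelial markers (0.131), chromatin repressors, interferon and cholesterol (each 0.158). For HIC1 targets (adjusted p = 0.416) the median of the mean ratios was -0.31 and their mean was 0.05. Median and mean also differed in sign for the cholesterol, p53, epithelial adhesion, fatty acid, leukocyte, hypoxia, DNA replication and apoptosis lists. Adjusted over the list alone, 4 of the 30 lists held genes with an adjusted p under 0.05, against 0 adjusted over all genes. These were CDKN1C among the HIC1 targets, ACP3 in the androgen list, VLDLR and DDIT4 in the stress response list, and S100A2 in the basal list. ACP3, which encodes prostatic acid phosphatase, was well above background on the HIC1 arrays only, so its call rests on GFP levels at background, and as bounds it was at least 1.84-fold higher in PC3 and 1.51-fold in C4-2B.

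Between the lines, NEFM, SMARCA4, LIN28B and others were well above background on 3 arrays and not on C4-2B-GFP, and CCL2, NPTX1 and FILIP1 were far brighter on C4-2B-GFP than on the other arrays. The neurofilament gene NEFM read 3.50, 4.35 and 3.69 on PC3-GFP, PC3-HIC1 and C4-2B-HIC1, the chromatin remodeller gene SMARCA4 3.57, 4.27 and 4.64, CKMT1A 2.01, 2.98 and 2.72, the RNA-binding protein gene LIN28B 0.77, 1.27 and 1.33, PNMA8A 1.06, 2.22 and 2.54, CALCA -0.03, 0.25 and -1.25, and PDZK1IP1 -0.17, 0.81 and -1.59. On C4-2B-GFP the brightest probe of each of these was not well above background, so no exact difference is given. UCHL1 was well above background on all 4 arrays, with -5.37 on C4-2B-GFP and between 4.23 and 5.17 elsewhere. UBD, which encodes a ubiquitin-like protein, was well above background on the PC3 arrays only, at -1.51 and -2.09. The chemokine gene CCL2 read 5.73 on C4-2B-GFP and between -1.39 and -0.39 elsewhere, NPTX1 5.25 and between -0.52 and 0.26, and FILIP1 0.63 and between -4.80 and -4.22. HKDC1, SERPIND1, RNF180, LRRC4, the growth factor receptor gene PDGFRA and PALM3 were well above background on both C4-2B arrays and on neither PC3 array, and CSF2RA on all but PC3-HIC1. These genes came from the ranking of mean differences over both vectors, which for most of them rests on levels at background.

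The prostate luminal list was not higher on C4-2B-GFP than on PC3-GFP, with a PC3 minus C4-2B median of 0.29, inside its random range. The basal and PC3-type list was lower on PC3-GFP than on C4-2B-GFP (median -0.67, below the range) and higher on PC3-HIC1 than on C4-2B-HIC1 (0.69, above the range). The HIC1 arrays of the lines were the most alike of all pairs, with a Pearson r of 0.990 across probes and 302 genes 2-fold apart. The GFP arrays had 1372 genes 2-fold apart (r 0.969), PC3-HIC1 and PC3-GFP 1063 (r 0.985), and C4-2B-HIC1 and C4-2B-GFP 2844 (r 0.947). With limma, 0 genes passed for PC3 over C4-2B, 206 had an unadjusted p under 0.05, and the smallest adjusted p was 0.9998. The differences between the lines on the HIC1 arrays and on the GFP arrays had a correlation of -0.14 across genes, so the arrays of a line did not pair in these data.

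**Figure D4:**
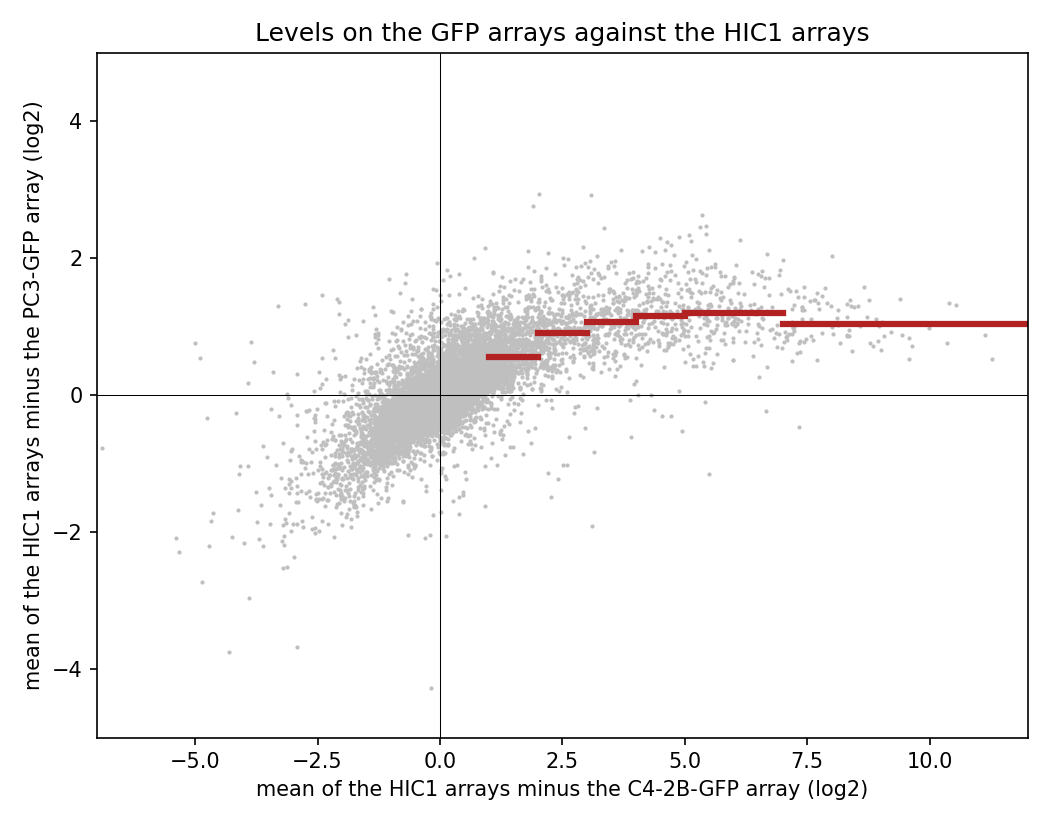
For each gene, the mean log2 level of the HIC1 arrays minus the level on C4-2B-GFP (horizontal axis) and minus the level on PC3-GFP (vertical axis), for genes well above background on both HIC1 arrays and on PC3-GFP but not always on C4-2B-GFP; red bars are medians within bins. The median shortfall on PC3-GFP is 0.57 where C4-2B-GFP falls short by 1 to 2 and stays between 0.90 and 1.20 from 2 to 12.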

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

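All tests that weigh an explanation in this part were chosen only after the result was seen. The rules that picked the results named at its end were fixed before the data were examined.

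The HIC1 arrays of the lines resembled each other more than any other pair of arrays did. A swap of labels as the only fault, among arrays that hold RNA of both lines, is argued against. Any such swap leaves C4-2B RNA on 2 arrays, where KLK3 should be abundant. The highest KLK3 level on any array was -7.98, not well above background, and this rests on 1 probe. KLK3 cannot test a swap among arrays of which none holds C4-2B RNA. What stays open is that the arrays labelled C4-2B hold RNA of other cells: luminal genes were no higher on C4-2B-GFP than on PC3-GFP (PC3 minus C4-2B median 0.29), which may be read as missing LNCaP lineage, and the sort for GFP would not remove transduced cells of another line. The basal and PC3-type list pointed both ways. It was lower on PC3-GFP than on C4-2B-GFP (-0.67), but higher on PC3-HIC1 than on C4-2B-HIC1 (0.69, 15 of 16 members), as the labels would have it. That HIC1 moved both lines to a shared state cannot be told apart from other cells behind the C4-2B labels. The 302 genes 2-fold apart between the HIC1 arrays, against 1372 between the GFP arrays, would follow from either. Replicate arrays and a typing of the cultures would decide.

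Genes low on C4-2B-GFP were also lower on PC3-GFP than on the HIC1 arrays, by an amount that levelled off. Among 451 genes 16-fold lower on C4-2B-GFP than on both HIC1 arrays, the PC3-GFP level was lower by a median of -1.14 log2, with quartiles of -1.44 and -0.90, or 45.2% of the HIC1 level. A mix with RNA like that of C4-2B-GFP is argued against: 35 genes 16-fold higher on C4-2B-GFP than on both HIC1 arrays stood on PC3-GFP at a median of -4.05 relative to it, where dilution to its share would give -0.87. A programme of HIC1 scaled by 1 factor in PC3, as the sole difference between the arrays, is argued against too. This was read over 1217 genes well above background on all 4 arrays and at least 2-fold lower on C4-2B-GFP. The slope of the PC3-GFP shortfall on that of C4-2B-GFP was 0.142 (bootstrap 95% interval 0.117 to 0.170, 2000 draws) where 1 factor would give 0.428. The interval covers the draw of genes only, not error between arrays or cultures. Levels particular to C4-2B-GFP would also lower the slope, so 1 factor alongside such differences is not excluded. A mix of RNA of the kind on the HIC1 arrays with RNA of other cells stays open. So, untested, does a programme that is weaker in PC3 in another form. The SD of the shortfall over the 451 genes was 1.28 times that between the HIC1 arrays. This does not decide on a mix, because the limit it was held to was set after the data were seen. Only 81 of the 451 genes were well above background on C4-2B-GFP.

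In PC3, 874 genes were higher and 189 lower. The genes 2-fold apart in C4-2B as the whole cause are argued against: without these 3603 genes, 155 were higher and 32 lower in PC3, so that 82.9% of calls were still higher. Signal near background cannot be told apart from a change confined to dim genes: among the dimmer genes, 28.9% of those 2-fold higher in C4-2B were also 2-fold higher in PC3, against 2.58% of those under 2-fold there, but an offset of both GFP arrays would give this too, and among the brighter genes 50.7% of calls were higher. A response to HIC1 stays among the open explanations, as untested.

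Among genes well above background on all 4 arrays, those that moved at least 2-fold in opposite directions in the lines were picked out by size. The differences were not tested. CNN1, a smooth muscle calponin gene, had a PC3 ratio higher than that of C4-2B by 4.24 log2 (1.77 against -2.47, the latter 0.92 with normexp). RASGRP2 differed by 4.001 (1.65 against -2.35). The immediate early gene EGR2 differed by 3.74 (1.63 against -2.11, the latter 1.12 with normexp), and the nuclear receptor gene NR4A1 by 3.13 (1.53 against -1.60). GEM, from the list of HIC1 targets, differed by 3.71 (2.19 against -1.52, the latter 0.18 with normexp). SCEL differed by -2.78 (-1.004 against 1.77, the former 0.28 with normexp).

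Probes without a gene symbol, which no comparison of genes used, also moved: of 7139 such probes well above background on all 4 arrays, 197 were 2-fold changed the same way in both lines, 78 higher and 119 lower.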

How the results depend on the processing

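The genes brighter than the median, the crossed pairing and normexp without spots of high background were chosen after seeing the data; the other alternatives were chosen before. Quantile normalisation and the authors' values each left 17 main results in place and moved 2. The additive fit gave 0 calls for HIC1 and for the lines under every alternative run. HIC1 was higher in both lines in each of the 5 settings of background or normalisation. Centring on the median put the median ratio of all genes at -0.08 in PC3 and -0.25 in C4-2B, and normexp put it at 0.13 and 0.16, so changes there are relative to those shifts. Among the named genes at least 2-fold apart and the lists outside their range, 16 directions reversed under normexp as planned and 1 under centring on the median. No direction among them reversed under normexp without spots of high background. Other genes were not followed singly. The crossed pairing gave 0 calls, with 2598 genes at an unadjusted p under 0.05. Leaving out an array was not possible with 1 per group. The mean in place of the median ended the calls of the mesenchymal and luminal lists in PC3 and of the HIC1 target, mesenchymal and epithelial lists in C4-2B, and added chromatin repressors in PC3 and neuroendocrine, heat shock and Notch lists in C4-2B.

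With normexp as planned, HIC1 stood at 0.89 in PC3 and 1.57 in C4-2B, and 81 genes were higher and 111 lower in PC3, 3990 higher in C4-2B and 45 higher in both, with r 0.859 across genes and 6 lists above their range in C4-2B. Reversed in PC3 were ACTG2 (0.38), S100A3 (0.31), KRT17 (0.56), MARCHF4 (0.41) and SCEL (0.28), and the medians of heat shock (-0.0731), TGF-beta (0.0098), ribosomal (-0.29) and cancer-testis genes (0.42). Reversed in C4-2B were S100A3 (0.64), CNN1 (0.92), EGR2 (1.12) and GEM (0.18), and the medians of HIC1 targets (0.18), epithelial adhesion (0.65) and cancer-testis genes (0.40). A few spots with background far above signal pulled the fitted background mean to -251, -663 and -720.1 on PC3-GFP, PC3-HIC1 and C4-2B-HIC1. Leaving out 11, 9 and 8 spots gave -4.35, -3.37 and -2.27, near the -4.19 of C4-2B-GFP. Fitted without them, HIC1 stood at 0.95 and 1.40, 339 genes were higher and 109 lower in PC3, and 175 were higher in both. None of the directions listed here as reversed turned in that fit.

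HIC1 in C4-2B was 1.68 with quantile normalisation and 1.66 in the authors' values, and each gave 4 lists higher over both lines in place of 2. Centring on the median gave HIC1 at 1.20 and 1.52, 2148 genes lower in C4-2B, -0.0314 for ribosomal proteins in PC3, and 3 lists lower over both lines in place of 6. The cause was not tested for these. With a correlation estimated from 1 residual degree of freedom 0 lists were higher and 0 lower.

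The looser background filter, which admits more genes, gave 353 lower in PC3 and 601 higher in both. The 3-fold threshold gave 172 higher and 40 lower in PC3, 759 and 604 in C4-2B, and 53 and 28 in both; the 1.5-fold threshold gave 1995 and 807, 2697 and 2710, and 964 and 577. The genes brighter than the median, with fewer genes tested, gave 75 and 73, 427 and 619, and 51 and 67.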

Other observations

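The genes named in this part were read from lists fixed before the data were examined or by the rule for named genes, and no explanation was tested here.

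Apoptosis regulators moved apart within their list, whose medians were near 0. The BH3-only genes BMF and BIK, which promote apoptosis, had log2 ratios of 1.84 and 1.35 in PC3 and of 2.70 and 2.48 in C4-2B. BIRC3 and CFLAR, which restrain caspases, stood at -1.60 and -0.65 in PC3 and at -3.42 and -2.93 in C4-2B. The dimmer CFLAR probes, also well above background on all 4 arrays, stood at -0.57 and -0.40 in PC3. In C4-2B the same probes differed, at -2.04 and 0.04, so the lower CFLAR level there was not shared by all its probes. Among p53 targets, SESN2 stood at 1.42 and 2.47 and the antiproliferative gene BTG2 at 1.11 and 3.82, while TP53I3 and GADD45A were lower in C4-2B (-2.16 and -1.84). In the cholesterol list, which was inside its random range in both lines, STARD4 stood at -0.89 in PC3 and -1.97 in C4-2B. CXCR4, the receptor of the chemokine CXCL12, was higher in PC3 by 2.12 and in C4-2B by at least 41.5-fold.

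The array labelled C4-2B-GFP stood apart at SMARCA4, an abundant gene on the other arrays. SMARCA4 read 3.57, 4.27 and 4.64 on PC3-GFP, PC3-HIC1 and C4-2B-HIC1 and was not well above background on C4-2B-GFP, and its second probe read 0.58, 1.35 and 2.09 in the same order and was not well above background there either. A dimmer probe, well above background on all 4 arrays, was lowest on C4-2B-GFP too, by less: it read -2.29 there, -1.75 and -1.53 on the PC3 arrays and -1.23 on C4-2B-HIC1. ZNF224 stood apart on PC3-GFP instead, at 1.55 against -2.56, -2.54 and -2.87 elsewhere.

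Markers of leukocytes gave no uniform picture: of 8 measured in PC3, TYROBP stood at 0.41 and CD8A at 0.34, and of 7 in C4-2B 0 were 2-fold apart. Probes of the same reference gene differed, as ACTB did in C4-2B, where its 4 probes stood at -0.62, -0.15, -1.12 and -1.22.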
